A study of Escherichia coli with 12 samples.

How the data were processed

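Total RNA was sequenced from 12 cultures of *Escherichia coli* JW3367, a strain of the BW25113 background that, as general knowledge, carries a deletion of *envZ*. Each culture held the plasmid pPCB together with pLCenvZ, labelled wild type, or pLCenvZM, labelled as mutated, and the nature of the mutation was not given in the sources used here. Cultures were diluted to an OD600 of 0.01 in LB with 0.5 mM IPTG and kept for 10 h at 37 °C under a red LED that was switched on and off with a period of 600, 900, 1200, 1800, 2400 or 3600 s. The design therefore crossed 2 constructs with 6 periods, with 1 library per combination, and the labels do not say whether cultures were repeated. Nor do they say whether all 12 were grown and sequenced together. Anything else shared by the cultures of a construct therefore cannot be told apart from the construct. All p-values measure only the spread between these 12 libraries.

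The deposited table holds 1 expression value on a log2 scale for each of 4069 genes in each library, normalized between libraries by the authors. Per the submitters' processing notes the tools were Bowtie2, HTSeq and DESeq2, with no versions and no stated roles. The transform was not named. Base 2 was inferred from the values, because base e would give single genes implausibly large counts, and every fold given here rests on that inference. Values ran from 0.0742 to 18.9 and library medians from 7.29 to 7.45. The deposited values hold no counts, so the depth of each library is unknown and no counting interval can be given. The spread between libraries was smaller for low genes, with a median SD over the 12 libraries of 0.0982 in the lowest decile of genes by mean and 0.215 in the highest, so differences of weakly expressed genes may be compressed by the transform. A 2nd deposited table gives the authors' principal component score, a coefficient per library for 2 components, from values not stated. The genome build used for alignment was not given in the sources used here. An annotation of *E. coli* MG1655 served to check gene names only: 3860 names equalled a reference symbol, 202 a synonym only, and 7 neither.

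Genes with a mean value of at least 1 were kept, which left 4039. Because the deposited values were already on a log scale, linear models were fitted to them directly with limma 3.58.1 in R 4.3.3, with a mean-variance trend and no robust option, where the plan for linear values had named a log2 transform with a pseudocount of 1. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, at a threshold of 0.05. The construct effect came from a model with construct and a 6-level period, so that it is the mean of 6 within-period differences with 5 residual degrees of freedom. The same model gave an F-test for any difference among periods. A trend common to both constructs used construct and the log2 of the period (9 residual degrees of freedom). Separate slopes for each construct and their difference came from a model with an interaction (8 residual degrees of freedom), and the intermediate-period response was tested as the squared centred log2 period. Slopes are log2 units per doubling of the period, and 600 to 3600 s is 2.58 doublings. For *envZ*, *ompR*, *ompF* and *ompC*, exact tests enumerated all 64 sign flips of the 6 within-period differences or all 720 orders of the 6 periods, two-sided, with adjustment over the 12 tests.

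A set of 46 gene lists (873 entries, of which 853 were tested) was written from textbook *E. coli* physiology before the data were examined, as were the models, the thresholds, the rule for named genes and all alternatives except 1. Lists were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the 46 lists within each comparison. Camera with an estimated correlation, and fry, which asks whether a list's genes move on balance one way without comparing them with other genes, were run beside it. The named-gene rule took *envZ*, *ompR*, *ompF* and *ompC*. It further took, for the construct effect, the common trend and the difference of trends, the 10 genes with the largest coefficient in each direction among those called, expressed at or above the median of tested genes (7.39) and, for the construct effect, with the same sign in all 6 periods (for the common trend, the same sign in both constructs). Where fewer than 5 passed in a comparison, the 5 with the smallest p replaced them. The 5 genes with the smallest p were taken for the other 2 tests, and *lacY*, *hemA*, *rpoS*, *fliC*, *csgD* and *tnaA* as reference genes. Of the 4 members with the smallest p that the rule gives for each list called by camera, the text gives the first 2, for every called list in the construct effect and for the 6 lists with the smallest camera p in the other comparisons. Called list members that moved against their list are also named, a choice made after the values were seen, and other genes named outside this rule are marked as such.

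Alternatives covered median-ratio rescaling, quantile normalization, limma without the trend, no filter and a 10 times stricter one, pseudocounts on the linear scale, a log2 change of at least 1, other scales of the period, other period terms, and leaving out each library and each period in turn. The added alternative, chosen after seeing the data, left out the 3 libraries farthest from the others of their construct, namely the wild-type library at 3600 s and the mutated libraries at 600 s and 900 s. For the construct effect, only the periods that kept a library of both constructs then entered the estimate. The procedure was tested on simulated data with 4039 genes of which 200 were changed. The construct test called 88.1% of genes changed by 0.5 and 98.5% of those changed by 1, with 14 calls among unchanged genes. The trend test called 79.1% of slopes of 0.25, the mutated slope 50.7% and the difference of slopes 34.3%, rising to 74.6% for a difference of 0.5. These rates hold for the simulated noise only. The simulation gave 7 calls among unchanged genes for the mutated slope. In the real libraries, another order of the periods gave up to 152 called genes for that slope. How far the rates hold where genes move together was not tested, so they may overstate performance, for the slopes in particular.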

Results

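Transcript levels of 4069 genes were measured in 12 libraries of *E. coli* JW3367 that expressed *envZ* from a plasmid, 6 with the wild-type construct and 6 with the mutated construct, 1 at each red-light period from 600 to 3600 s, so that no combination was replicated. EnvZ is the histidine kinase that phosphorylates the response regulator OmpR, and OmpR in turn controls the porin genes *ompF* and *ompC*. The series was described as a comparison of expression under light signals of different frequency. Library depth is unknown because the deposited values are normalized. Libraries of 1 construct differed from one another by a median root mean square of 0.232 (wild type) and 0.263 (mutated) log2 units over genes, and libraries of different constructs by a median of 0.440. The authors' deposited coefficients of the 2nd component were negative in all 6 wild-type libraries (-0.374 to -0.174) and positive in all 6 mutated libraries (0.104 to 0.508). Among the libraries of its construct, the wild-type library at 3600 s lay farthest from the others (median root mean square difference 0.359), and so did the mutated libraries at 600 s (0.372) and 900 s (0.289), against 0.186 to 0.233 for the remaining 9.

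**Figure D1:**
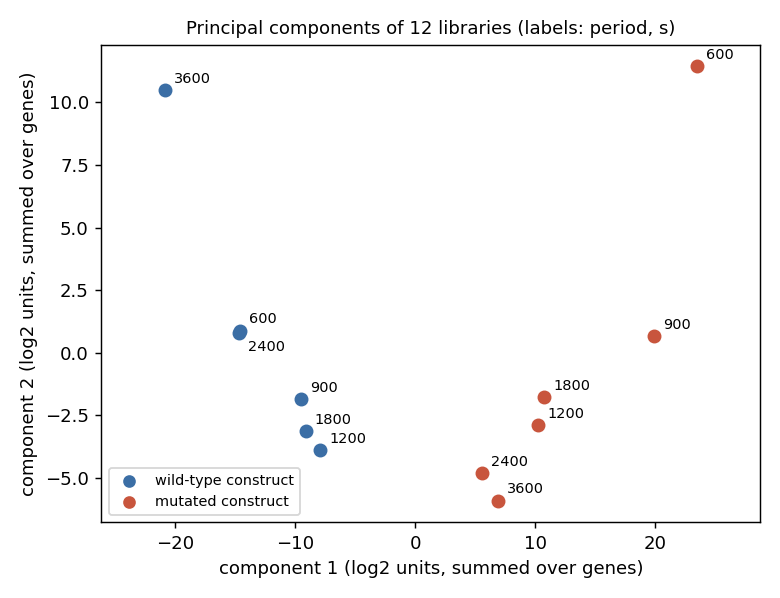
First and second principal components of the 12 libraries (log2 units, 1 point per library, labelled with the light period in s), coloured by construct. Component 1 ran from -20.8 to -7.93 in the wild-type libraries and from 5.53 to 23.4 in the mutated libraries.

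Of the genes of the system that the plasmids altered, only *ompF* passed the test between constructs. The mean differences of *ompF* and *envZ* were larger in size than the median over all genes that passed (0.35). A missing call therefore does not mean a small difference. The porin gene *ompF* was higher in the mutated libraries by 0.42 ± 0.10 (log2, SE, n = 6 within-period differences), a 1.34-fold difference seen in 6 of 6 periods (adjusted p = 0.0115). The *envZ* transcript itself, lower in 5 of 6 periods, lay at -0.39 ± 0.16 (adjusted p = 0.086), the *ompR* transcript at -0.13 ± 0.06 (adjusted p = 0.1004) and *ompC* at -0.12 ± 0.12 (adjusted p = 0.454), and none of these 3 passed the test. Over the alternative settings the *ompC* difference ran from -0.24 to -0.03 and never passed. If the strain carries the deletion of *envZ* named above, most of the *envZ* value should come from the plasmid copy. Its differences and slopes would then be those of the plasmid transcript. Values of *ompR* lay well below those of *envZ*, at 10.29 to 10.59. Because the alignment reference was not given, it is unknown whether any chromosomal remnant adds to the *envZ* value, or which parts of the construct it covers. Levels of *envZ* were 14.65 to 15.49 in the wild-type and 14.44 to 15.13 in the mutated libraries, and those of *ompF* 14.26 to 14.60 and 14.48 to 15.12. In the mutated libraries *ompF* fell by 0.26 ± 0.07 per doubling of the period (adjusted p = 0.0477), *ompC* had a slope of -0.35 ± 0.09 (adjusted p = 0.0516) and *envZ* one of 0.28 ± 0.10 (adjusted p = 0.119). In the wild-type libraries the slopes were -0.05 ± 0.07 for *ompF*, -0.02 ± 0.09 for *ompC* and -0.16 ± 0.10 for *envZ* (adjusted p = 0.847, 0.962 and 0.593). The differences of slope did not pass for *ompF* (-0.21, adjusted p = 0.517), *ompC* (-0.33, adjusted p = 0.433) or *envZ* (0.44, adjusted p = 0.318), and without the wild-type library at 3600 s those of *ompC* and *envZ* were -0.22 and 0.23. The *ompR* slopes were 0.02 ± 0.04 in the wild-type and -0.03 ± 0.04 in the mutated libraries, with a difference of -0.06 (adjusted p = 0.798).

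By exact sign flips, the *ompF* difference between constructs reached p = 0.03125, the smallest value that 6 pairs can give, and an adjusted exact p of 0.125. Exact tests of the mutated slopes gave p = 0.00833 for *envZ* and p = 0.0111 for *ompF* (adjusted exact p = 0.0667 each), p = 0.0583 for *ompC* (adjusted exact p = 0.175) and p = 0.428 for *ompR*. In the other exact tests p was 0.09375 for the construct difference of both *envZ* and *ompR*, 0.5 for that of *ompC*, and 0.331 (*envZ*) to 0.831 (*ompC*) for the wild-type slopes. The *envZ* difference passed without the 3600 s period or either of its libraries (-0.56, adjusted p = 0.00966 without the period), after quantile normalization (-0.46, adjusted p = 0.0203) and without the 3 libraries that stood apart (-0.48, adjusted p = 0.0177). The last of these values rests only on the periods that kept a library of both constructs. The *envZ* slope in the mutated libraries passed without the wild-type library at 3600 s (adjusted p = 0.0305). The *ompC* slope passed without that library (adjusted p = 0.0354), without the mutated library at 1200 s (adjusted p = 0.0463) and without the 1200 s period (adjusted p = 0.043). It also passed without the 3600 s period (-0.45, adjusted p = 0.048) and with the rank of the period (adjusted p = 0.0407). Without the 3 libraries that stood apart it was -0.17 (adjusted p = 0.997). The *ompF* slope lost its call in 21 of 31 settings, with values of -0.29 to -0.18. The 4 genes were not called as a list (camera adjusted p = 0.732). Of the 12 other members of the OmpR regulon tested, 2 were higher and 4 lower in the mutated libraries, the same counts when adjusted over the list alone (camera adjusted p = 0.537).

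**Figure D2:**
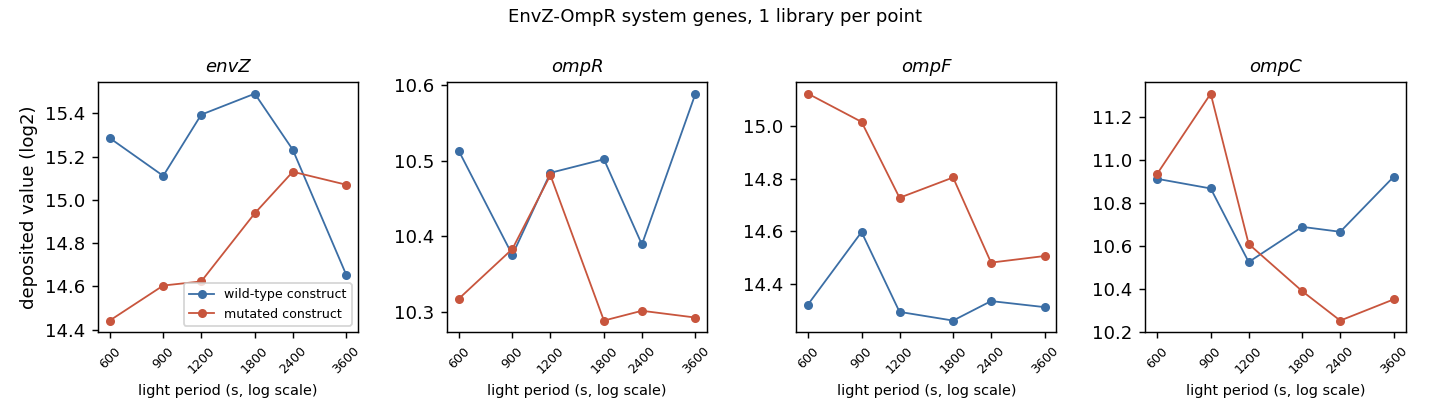
Deposited log2 values of *envZ*, *ompR*, *ompF* and *ompC* against the light period (s, log scale), 1 library per point and 1 line per construct. The *ompF* values of the mutated construct lay above those of the wild-type construct at each of the 6 periods.

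The comparison of constructs asked which transcripts differed between cells with the wild-type and the mutated *envZ* plasmid at matched light periods. The largest differences were in glycerol metabolism, where 9 of 9 tested genes were higher in the mutated libraries, also 9 when adjusted over the list alone. The dehydrogenase gene *glpA* was higher by 3.90 ± 0.22 (log2, SE, n = 6, 14.9-fold, adjusted p = 1.07e-05), and its operon partners *glpB* by 3.34 ± 0.20 and *glpC* by 3.07 ± 0.22. The glycerol facilitator gene *glpF* was higher by 2.84 ± 0.09 (adjusted p = 5.32e-07), the kinase gene *glpK* by 2.99 ± 0.11, *glpD* by 2.79 ± 0.11, and the glycerol phosphate uptake and hydrolysis genes *glpT* and *glpQ* by 3.02 ± 0.14 and 2.65 ± 0.13. The list was called higher (camera adjusted p = 4.92e-11, adjusted p = 0.567 with an estimated correlation). Its median lay 0.547 and 0.664 above the other mutated libraries in those at 600 s and 900 s. Beyond glycerol, *fruB* of the fructose phosphotransferase system was higher by 3.56 ± 0.16 (adjusted p = 3.2e-06). The nitrate transporter gene *narK* was higher by 2.43 ± 0.69 (adjusted p = 0.022), a value that dropped to 1.53 without the 600 s period or either library at 600 s.

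The genes with the largest negative differences included those of the *ast*, *acs* and *isc* operons, none of which forms a list of its own. The arginine succinyltransferase operon gave -2.22 ± 0.24 for *astA* (log2, SE, n = 6, adjusted p = 0.000333), -1.89 ± 0.22 for *astB*, -1.79 ± 0.23 for *astC* and -1.75 ± 0.24 for *astD*. The acetyl-CoA synthetase gene *acs* lay at -1.97 ± 0.21 (adjusted p = 0.00033) and its neighbour *actP*, an acetate permease gene, at -1.39 ± 0.22 (adjusted p = 0.00154). Of the *isc* operon, *iscU* lay at -1.69 ± 0.27 (adjusted p = 0.0018), *iscS* at -1.67 ± 0.31, *iscR* at -1.50 ± 0.32 (adjusted p = 0.00654) and *iscX* at -1.31 ± 0.13. The wild-type libraries were split for *iscS*, at 12.50, 12.34 and 13.27 at 600, 2400 and 3600 s against 10.71 to 10.99 at 900, 1200 and 1800 s. The gene *astA* was split alike, at 10.99, 11.01 and 11.43 against 9.99 to 10.08. This grouping does not follow the order of the periods. Without the 3 libraries that stood apart, *iscS* was -1.06, *iscU* -1.12, *iscR* -0.90 and *astD* -1.16, each still called. These estimates rest only on the periods that kept a library of both constructs, namely 1200, 1800 and 2400 s.

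Motility genes were higher in the mutated libraries as a group. Of 53 tested flagella and chemotaxis genes, 46 were higher, 1, the aerotaxis receptor gene *aer*, was lower, and 6 did not pass, against 47 higher and 1 lower when adjusted over the list alone. The flagellin gene *fliC* was higher by 1.58 ± 0.13 (SE, n = 6, 2.99-fold, adjusted p = 0.000112) and the chemotaxis kinase gene *cheA* by 0.90 ± 0.10 (adjusted p = 0.000426). The list test gave camera adjusted p = 2.36e-13, adjusted p = 0.567 with an estimated correlation. In the mutated libraries at 600 s and 900 s the list's median lay 0.812 and 0.566 above the other mutated libraries. Type 1 fimbriae genes were higher in 5 of 9 cases and lower in none, 6 when adjusted over the list alone (camera adjusted p = 0.0123, adjusted p = 0.567 with an estimated correlation). Examples were the major subunit gene *fimA* at 0.78 ± 0.09 and the recombinase gene *fimB* at 0.62 ± 0.10. Acid resistance genes were higher in 15 of 21 cases, 17 when adjusted over the list alone, and lower in none (camera adjusted p = 3.03e-07, adjusted p = 0.567 with an estimated correlation). The periplasmic chaperone gene *hdeA* was higher by 1.43 ± 0.17 (adjusted p = 0.000575) and the glutamate antiporter gene *gadC* by 1.80 ± 0.22 (adjusted p = 0.000583). The acid resistance median lay 0.757 above the other mutated libraries in the one at 900 s, and -0.277 from the other wild-type libraries in the one at 3600 s.

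**Figure D3:**
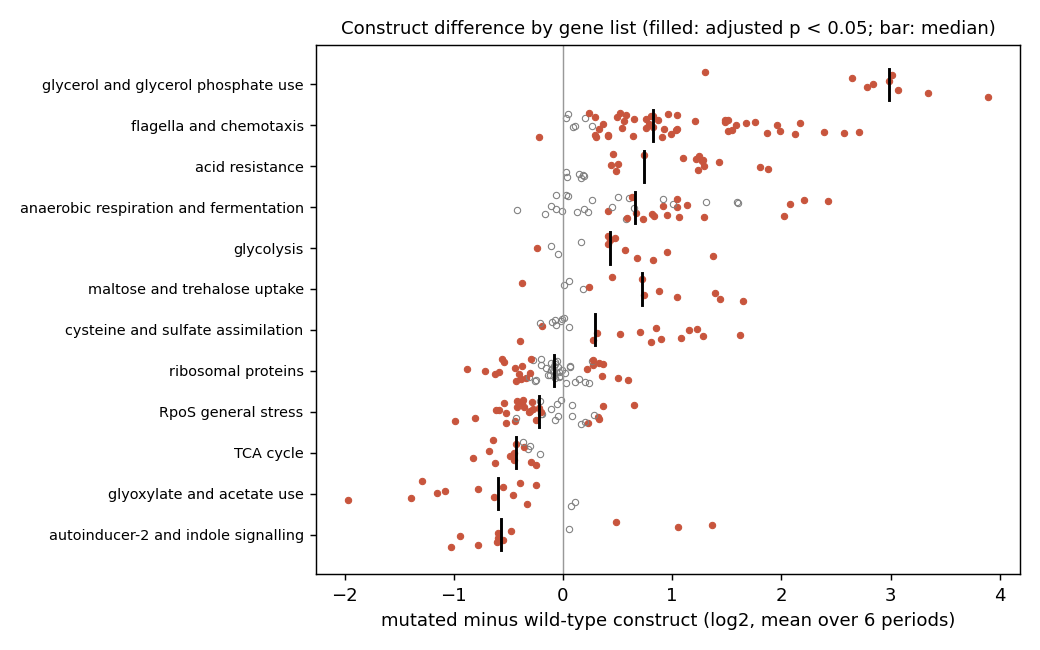
Difference between constructs (mutated minus wild type, log2, mean of 6 periods) for each tested gene of 12 lists chosen for display after the values were seen; filled points passed the gene test and black bars are medians. The glycerol list has a median of 2.99, the flagella list 0.828 and the list for glyoxylate and acetate use -0.591.

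Central carbon metabolism differed by branch. Of 13 glycolysis genes, 9 were higher and 1, *pfkB*, lower, 10 and 1 when adjusted over the list alone, with the mutase gene *gpmM* at 0.95 ± 0.05 (SE, n = 6, adjusted p = 4.91e-06) and the enolase gene *eno* at 0.83 ± 0.08 (camera adjusted p = 0.000456, adjusted p = 0.567 with an estimated correlation). Of 15 TCA cycle genes, 11 were lower and none higher, 14 when adjusted over the list alone. The fumarase gene *fumC* lay at -0.45 ± 0.06 and the aconitase gene *acnB* at -0.63 ± 0.08 (camera adjusted p = 3.14e-05, adjusted p = 0.567 with an estimated correlation). Genes for glyoxylate and acetate use were lower in 12 of 14 cases, also 12 when adjusted over the list alone (camera adjusted p = 3.47e-05, adjusted p = 0.567 with an estimated correlation). Besides *acs*, the glycolate oxidase gene *glcE* was among them, at -1.08 ± 0.13. Genes for anaerobic respiration and fermentation were higher in 18 of 40 cases and lower in none, 26 when adjusted over the list alone (camera adjusted p = 5.08e-05, adjusted p = 0.567 with an estimated correlation). Examples were the dimethyl sulfoxide reductase genes *dmsB* at 1.06 ± 0.14 and *dmsC* at 0.84 ± 0.12. In the wild-type library at 3600 s the TCA list lay -0.289 and the anaerobic list -0.351 from the other wild-type libraries. The mutated libraries at 600 s and 900 s lay at -0.203 and -0.276 from the other mutated libraries for the TCA list, -0.16 and -0.208 for glyoxylate and acetate use, and 0.157 and 0.129 for glycolysis. Maltose and trehalose uptake genes were higher in 9 of 13 cases and lower in 1, the activator gene *malT*, with the same counts when adjusted over the list alone. The maltoporin gene *lamB* was higher by 1.65 ± 0.17 and the transport ATPase gene *malK* by 1.39 ± 0.15 (camera adjusted p = 0.000587, adjusted p = 0.567 with an estimated correlation). The maltose median lay 0.491 above the other mutated libraries in the one at 600 s and 0.361 above them at 900 s.

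Among biosynthesis lists, cysteine and sulfate assimilation was higher in 12 of 22 genes and lower in 2, *cysB* and *ssuB*, the same when adjusted over the list alone. The sulfite reductase gene *cysJ* was higher by 1.62 ± 0.15 (SE, n = 6, adjusted p = 0.000154) and the sulfate transporter gene *cysU* by 1.23 ± 0.13 (camera adjusted p = 0.0123, adjusted p = 0.609 with an estimated correlation). The list lay -0.2 from the other wild-type libraries in the one at 3600 s and 0.172 above the other mutated libraries in the one at 900 s. Methionine genes were higher in 7 of 13 cases and lower in none, also 7 when adjusted over the list alone (camera adjusted p = 0.0123, adjusted p = 0.589 with an estimated correlation). Examples were *metK* at 0.80 ± 0.11 and *metN* at 0.57 ± 0.08, and the list lay 0.167 above the other mutated libraries in the one at 600 s. Branched-chain amino acid genes were lower in 7 of 13 cases and higher in none, also 7 when adjusted over the list alone (camera adjusted p = 0.00266, adjusted p = 0.567 with an estimated correlation). Examples were *leuC* at -0.66 ± 0.07 and *leuD* at -0.63 ± 0.07. The branched-chain median lay 0.306 above the other wild-type libraries in the one at 3600 s, and -0.134 and -0.141 from the other mutated libraries in those at 600 s and 900 s. Iron acquisition genes were lower in 6 of 33 cases and higher in 1, *fhuB*, but 3 and 0 when adjusted over the list alone. The energy-transducing genes *tonB* and *exbD* lay at -0.67 ± 0.11 and -0.52 ± 0.11 (camera adjusted p = 0.018, adjusted p = 0.609 with an estimated correlation), and the list's median in the wild-type library at 3600 s lay 0.532 above the other wild-type libraries.

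Stress and signalling lists moved in both directions. RpoS-dependent genes were lower in 20 of 39 cases and higher in 5 (*bolA*, *elaB*, *wrbA*, *yciE* and *glgS*), 23 and 7 when adjusted over the list alone. The gene for the general stress sigma factor, *rpoS*, lay at -0.61 ± 0.09 (SE, n = 6, adjusted p = 0.00124), *csiD* at -0.99 ± 0.12 and *psiF* at -0.58 ± 0.07 (camera adjusted p = 0.00241, adjusted p = 0.609 with an estimated correlation). Toxin-antitoxin genes were lower in 10 of 21 cases and higher in none, 11 when adjusted over the list alone (camera adjusted p = 0.000896, adjusted p = 0.567 with an estimated correlation). Examples were *hokD* at -0.72 ± 0.06 and *mazF* at -0.50 ± 0.07. The toxin-antitoxin median in the mutated libraries at 600 s and 900 s lay -0.204 and -0.156 from the other mutated libraries. SOS response genes were lower in 9 of 21 cases and higher in 1, *lexA*, the same when adjusted over the list alone (camera adjusted p = 0.0449, adjusted p = 0.6 with an estimated correlation). Examples were *recN* at -0.34 ± 0.06 and *dinI* at -0.42 ± 0.07. The SOS median lay -0.072 from the other mutated libraries in the one at 600 s, with 10 of 21 genes below all 5 others and 1 above them. Heat shock genes were higher in 8 of 21 cases and lower in none, also 8 when adjusted over the list alone (camera adjusted p = 0.0116, adjusted p = 0.609 with an estimated correlation). Examples were the heat shock sigma factor gene *rpoH* at 0.41 ± 0.06 and *htpX* at 0.39 ± 0.09, which was 0.59 without the 3 libraries that stood apart. The heat shock median lay -0.435 from the other wild-type libraries in the one at 3600 s and -0.216 from the other mutated libraries in the one at 900 s. Multidrug efflux genes were higher in 10 of 20 cases and lower in 1, *acrB*, 11 and 1 when adjusted over the list alone (camera adjusted p = 0.0123, adjusted p = 0.567 with an estimated correlation). Examples were *acrD* at 0.54 ± 0.07 and *mdtC* at 0.50 ± 0.07. In the list for autoinducer-2 and indole signalling, 8 of 12 genes were lower and 3 higher, the same when adjusted over the list alone (camera adjusted p = 0.0362, adjusted p = 0.609 with an estimated correlation). The autoinducer-2 uptake and processing genes *lsrA* and *lsrG* lay at -1.03 ± 0.08 and -0.94 ± 0.10. The tryptophanase gene *tnaA*, whose product makes indole, was instead higher by 1.05 ± 0.14 and its neighbour *tnaB* by 1.36 ± 0.15. This list lay -0.401 from the other wild-type libraries in the one at 3600 s, and the RpoS list 0.205 above the other mutated libraries in the one at 900 s. Of the remaining reference genes, *csgD*, a curli regulator gene, lay at -0.27 ± 0.06 (adjusted p = 0.0111), *hemA* at 0.19 ± 0.06 (adjusted p = 0.0358) and *lacY* at -0.12 ± 0.10 (adjusted p = 0.36). Without the 3 libraries that stood apart *csgD* was -0.15 (adjusted p = 0.214) and *hemA* 0.10 (adjusted p = 0.349). Both values, like that of *htpX*, rest only on the periods that kept a library of both constructs. The *hemA* call was lost without any period except 1200 s, at 0.16 to 0.20. Leaving out either library of a period gave the same estimate as leaving out that period.

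In all, limma called 1599 of 4039 genes between constructs, 830 higher and 769 lower in the mutated libraries, against 1993 genes at an unadjusted p under 0.05 where chance would give 202. Of the 1599 called, 128 differed by a log2 value of at least 1 (89 higher, 39 lower), and 1329 had the same sign in all 6 periods. For 867 genes (21.5%) all 6 mutated libraries lay on one side of all 6 wild-type libraries, where chance gives 0.217%. The median difference over all genes was -0.01. Camera called 19 of the 46 lists (11 higher, 8 lower), none with an estimated correlation, and fry called 24. For outer membrane proteins, amino acid catabolism and arginine biosynthesis, none of them called, the median, mean and test differed in sign. Without the 3 libraries that stood apart, 630 genes were higher and 550 lower, of which 1031 were among the 1599. These counts rest only on the periods that kept a library of both constructs.

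The comparison of periods asked which transcripts followed the frequency of the light signal. No gene passed the limma test for a trend common to both constructs (0 of 4039, 869 at an unadjusted p under 0.05, smallest adjusted p = 0.121), nor did any by limma without a variance trend. The genes with the smallest p were *proW*, a gene of the glycine betaine transporter, at -0.26 ± 0.05 (log2 per doubling, SE, n = 12), *hisG* of histidine biosynthesis at 0.17 ± 0.03, the bacterioferritin gene *bfr* at -0.21 ± 0.04, *ytfL* at 0.16 ± 0.03 and *fruK* of the fructose operon at 0.24 ± 0.05, each with adjusted p = 0.121. Among reference genes, *fliC* had a slope of -0.21 ± 0.08 (adjusted p = 0.17), *tnaA* -0.28 ± 0.11 (adjusted p = 0.191, with -0.07 without the 3600 s period, -0.11 without the wild-type library at 3600 s and -0.54 without the 600 s period), *lacY* 0.10 ± 0.06, *csgD* 0.04 ± 0.04, *rpoS* 0.03 ± 0.05 and *hemA* -0.02 ± 0.03. Without the 3600 s period the *fliC* slope was -0.33 and that of *lacY* 0.03, and without the wild-type library at 600 s that of *lacY* was 0.16. The common slopes of *envZ*, *ompR*, *ompF* and *ompC* were 0.06 ± 0.09, -0.00367 ± 0.03, -0.15 ± 0.05 and -0.18 ± 0.08 (adjusted p = 0.735, 0.967, 0.16 and 0.206), with those of *envZ* and *ompC* at 0.20 without the wild-type library at 3600 s and -0.29 without the 3600 s period.

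As lists, ribosomal protein genes were higher at longer periods, although none of the 54 passed singly and 1 did when adjusted over the list alone (camera adjusted p = 5.92e-15, adjusted p = 0.443 with an estimated correlation). The slopes of *rpmI* and *rpmA* were 0.21 ± 0.04 and 0.15 ± 0.04 (SE, n = 12), and 0.08 and 0.02 without the 3 libraries that stood apart (*rpmA* 0.09 without the 3600 s period). The ribosomal list also moved with single libraries, at 0.538 from the other wild-type libraries in the one at 3600 s, -0.211 from the other mutated libraries in the one at 600 s and -0.325 in the one at 900 s. Flagella and chemotaxis genes were lower at longer periods, with 0 of 53 genes passing and 29 when adjusted over the list alone (camera adjusted p = 3.47e-14, adjusted p = 0.442 with an estimated correlation). The genes *flhA* and *flgL* had slopes of -0.34 ± 0.08 and -0.29 ± 0.08, and -0.12 and -0.15 without the 3 libraries that stood apart. This list lay 0.812 and 0.566 above the other mutated libraries at 600 s and 900 s, and its median slope in the wild-type libraries was -0.00555. Acid resistance genes were also lower, with 0 of 21 genes passing and 12 when adjusted over the list alone (camera adjusted p = 1.82e-06, adjusted p = 0.442 with an estimated correlation). Examples were *slp* and *hdeA* at -0.38 ± 0.09 and -0.36 ± 0.10, and -0.16 and -0.11 without the 3 libraries that stood apart. Acid resistance genes lay 0.757 and 0.28 above the other mutated libraries at 900 s and 600 s, and -0.277 from the other wild-type libraries at 3600 s. Maltose and trehalose uptake genes were lower as well, with 0 of 13 passing and 9 when adjusted over the list alone (camera adjusted p = 2.15e-05, adjusted p = 0.402 with an estimated correlation). Examples were *malE* and *lamB* at -0.43 ± 0.09 and -0.44 ± 0.10, and -0.14 and -0.19 without the 3 libraries that stood apart. The maltose list lay 0.491 and 0.361 above the other mutated libraries at 600 s and 900 s, and -0.194 from the other wild-type libraries at 3600 s. Toxin-antitoxin genes were higher at longer periods, with 0 of 21 passing under either adjustment, adjusted over the list alone or over all genes (camera adjusted p = 0.000287, adjusted p = 0.402 with an estimated correlation). Examples were *hokD* and *mqsR* at 0.14 ± 0.04 and 0.27 ± 0.08 (0.05 and -0.01 without the 3 libraries that stood apart), and the list moved with the mutated libraries at 600 s and 900 s (-0.204 and -0.156 from the other mutated libraries). Genes for anaerobic respiration and fermentation were lower, with 0 of 40 passing and 1 when adjusted over the list alone (camera adjusted p = 0.000626, adjusted p = 0.446 with an estimated correlation). Examples were *dcuC* and *focA* at -0.20 ± 0.04 and -0.20 ± 0.06, and -0.12 and -0.09 without the 3 libraries that stood apart. This list lay -0.351 from the other wild-type libraries at 3600 s, and its nitrate transporter gene *narK* was 5.01 higher in the mutated library at 600 s than the mean of the other mutated libraries.

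Camera called 22 of the 46 lists for the common trend (8 higher, 14 lower), none with an estimated correlation, and fry called 9. For TCA cycle, ATP synthase, histidine biosynthesis, heat shock and PhoPQ lists, none of them called, the median, mean and test differed in sign. Without the wild-type library at 600 s, 155 genes passed for the common trend, among them *malE*, *lamB*, *proW* and *hisG*, and 1 passed without the 3 libraries that stood apart or with the period in seconds. A difference of any kind among periods was likewise not called by limma for any gene (0 of 4039, 212 at an unadjusted p under 0.05 where chance would give 202, smallest adjusted p = 0.752), with or without a variance trend. It was called for 45 genes without the wild-type library at 600 s and 10 without the mutated library at 3600 s. The genes with the smallest p in this test were the RNA helicase gene *deaD*, *nsrR*, *ftnB*, *nfuA* and *ycaC*, whose period means spanned 0.71, 0.63, 0.54, 0.73 and 0.80 log2 units (adjusted p = 0.752 each). The spans of *envZ*, *ompR*, *ompF* and *ompC* were 0.36, 0.14, 0.40 and 0.63 (adjusted p = 0.889, 0.924, 0.752 and 0.752).

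Whether the response to period depended on the construct was tested through the slope within each construct and the difference of slopes. In the mutated libraries, flagellar genes fell steeply as the period lengthened, while their slopes in the wild-type libraries lay near 0. The list's median in the wild-type libraries was only 5.07 to 5.20, below the median of tested genes (7.39). Low expression and the lack of a response to the period therefore cannot be told apart in the wild-type libraries. The flagellar sigma factor gene *fliA* fell by 0.91 ± 0.09 per doubling in the mutated libraries (SE, n = 6, adjusted p = 0.000369) and had a slope of 0.10 ± 0.09 in the wild-type libraries (adjusted p = 0.729), a difference of -1.01 ± 0.12 (adjusted p = 0.00742). The hook gene *flgE* and the hook-cap gene *flgD* differed in slope by -1.19 ± 0.17 and -1.14 ± 0.17, the rod gene *flgG* by -1.15 ± 0.18 (adjusted p = 0.0148 each) and the P-ring gene *flgI* by -0.95 ± 0.12 (adjusted p = 0.00742). In the mutated libraries *fliA* went from 8.182 at 600 s to 6.005 at 3600 s, and in the wild-type libraries it stayed between 5.07 and 5.36. The flagellin gene *fliC* fell by 0.39 ± 0.09 per doubling in the mutated libraries (adjusted p = 0.0277), with a difference of slopes of -0.37 ± 0.12 that did not pass (adjusted p = 0.345). The *fliC* slope lost its call without the mutated library at 600 s, 900 s or 2400 s (-0.43, -0.34 and -0.33). Of 53 flagella and chemotaxis genes, 17 differed in slope, all lower in the mutated libraries, and 39 did when adjusted over the list alone (camera adjusted p = 1.1e-43, adjusted p = 0.203 with an estimated correlation).

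**Figure D4:**
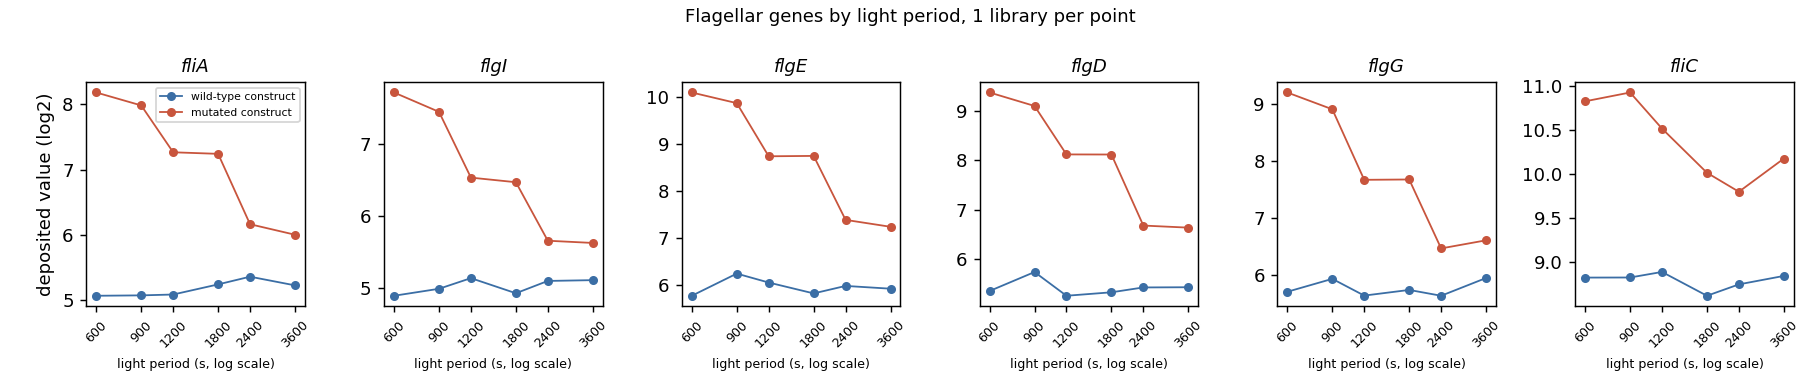
Deposited log2 values of *fliA*, *flgI*, *flgE*, *flgD*, *flgG* and *fliC* against the light period (s, log scale), 1 library per point and 1 line per construct. In the mutated libraries *flgE* went from 10.10 at 600 s to 7.24 at 3600 s, and in the wild-type libraries it lay between 5.78 and 6.25.

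Other lists differed in slope without any single gene passing over all genes tested. Glycerol genes were lower at longer periods in the mutated relative to the wild-type libraries, 7 of 9 when adjusted over the list alone, with *glpB* and *glpA* at -0.62 ± 0.15 and -0.65 ± 0.17 (SE, n = 12; camera adjusted p = 1.31e-07, adjusted p = 0.471 with an estimated correlation). The value of *glpA* was -0.40 without the wild-type library at 600 s. Maltose and trehalose uptake genes showed the same direction, 5 of 13 when adjusted over the list alone (camera adjusted p = 2.06e-05, adjusted p = 0.471 with an estimated correlation). Examples were *malM* and *malK* at -0.30 ± 0.09 and -0.39 ± 0.12, the latter -0.23 without the wild-type library at 600 s. The mutated libraries at 600 s and 900 s lay 0.547 and 0.664 above the other mutated libraries for the glycerol list, and 0.491 and 0.361 for the maltose list. TCA cycle genes had the opposite direction, with 0 of 15 passing when adjusted over the list alone (camera adjusted p = 7.71e-06, adjusted p = 0.555 with an estimated correlation). Examples were *sucC* and *sdhB* at 0.43 ± 0.14 and 0.31 ± 0.11. Both turned to -0.09 without the 3 libraries that stood apart. Iron acquisition genes were lower in slope, with 0 of 33 passing when adjusted over the list alone (camera adjusted p = 0.000107, adjusted p = 0.708 with an estimated correlation). Examples were *fecI* and the enterobactin synthesis gene *entC* at -0.33 ± 0.08 and -0.78 ± 0.27, the latter -0.21 without the wild-type library at 3600 s. Heat shock genes were higher in slope, with 1 of 21 passing when adjusted over the list alone (camera adjusted p = 0.000109, adjusted p = 0.708 with an estimated correlation). Examples were *hspQ* and the co-chaperone gene *dnaJ* at 0.34 ± 0.09 and 0.37 ± 0.15, the latter between 0.08 without the 3600 s period and 0.73 without the 600 s period. Of single genes, *fecI* passed without the wild-type library at 1800 s (adjusted p = 0.0248) and *glpB* and *fliC* without the mutated library at 3600 s (adjusted p = 0.0384 and 0.0478). In the wild-type library at 3600 s the lists that moved with it lay at -0.289 (TCA cycle), 0.532 (iron acquisition) and -0.435 (heat shock) from the other wild-type libraries. In the mutated libraries at 600 s and 900 s they lay at -0.203 and -0.276 (TCA cycle) from the other mutated libraries. The values there were 0.0607 and -0.0087 for iron acquisition and 0.0841 and -0.216 for heat shock. Slope differences of the reference genes did not pass, with *rpoS* at 0.19 ± 0.09, *tnaA* at 0.22 ± 0.22, *lacY* at 0.12 ± 0.11, *hemA* at -0.06 ± 0.06 and *csgD* at -0.02 ± 0.08 (adjusted p from 0.544 for *rpoS* to 0.953 for *csgD*).

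In total limma called 17 genes for the difference of slopes (0 higher, 17 lower, 385 at an unadjusted p under 0.05), and all 17 belong to the flagella and chemotaxis list. In the mutated libraries 173 genes had a slope (39 higher, 134 lower at longer periods), 34 of the 134 from that list. In the wild-type libraries none did (0 of 4039, 377 at an unadjusted p under 0.05, smallest adjusted p = 0.518), also without a variance trend. Camera called 13 of the 46 lists for the difference of slopes (7 higher, 6 lower), none with an estimated correlation, and fry called 1. For outer membrane proteins, RpoS general stress, translation factors, other sugar and polyol use and cold shock, none of them called, the median, mean and test differed in sign. The count of 17 went to 0 without the wild-type library at 600 s, 10 without that at 900 s, 11 without that at 2400 s and 3 without that at 3600 s. Its value was 1, 34 and 11 without the mutated libraries at 600, 1200 and 2400 s. It went to 0, 7, 30, 11, 1 and 1 without the periods from 600 to 3600 s in turn, and to 0 with the period in seconds or without the 3 libraries that stood apart. Without the mutated library at 600 s, 16 of the 173 genes were left, all lower, and counts of 89, 83 and 42 lower genes were found without the wild-type library at 900 s and the mutated libraries at 1800 and 2400 s. Leaving out the periods of 600, 900, 1800 and 2400 s gave 24, 47, 74 and 36 genes that were lower. The count of 39 went to 17 and 92 without the wild-type libraries at 900 and 3600 s, and to 0, 8, 78, 13, 3 and 21 without the mutated libraries from 600 to 3600 s in turn. It was 0, 2, 72, 13 and 4 without the periods from 600 to 2400 s in turn. Without the 3 libraries that stood apart no slope was called in the mutated libraries, although those of *fliA* (-0.91, adjusted p = 0.451), *flgD* (-1.10) and *flgE* (-1.10) were about as steep as before and those of *flgI* (-0.66) and *flgG* (-0.81, adjusted p = 0.529) less so.

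A response that peaked or dipped at intermediate periods was tested because a straight trend would miss it. The genes with the smallest p were the ferritin-like gene *ftnB*, with a squared term of -0.25 ± 0.04 (SE, n = 12, adjusted p = 0.382), the reductase gene *ynfF* at -0.84 ± 0.20, *tnaA* at -0.39 ± 0.10, *tnaB* at -0.44 ± 0.11 and *ybgS* at 0.21 ± 0.05 (adjusted p = 0.686 each). A negative term means higher values between the extremes of period than at them. The squared terms of *envZ*, *ompR*, *ompF* and *ompC* were -0.15 ± 0.11, 0.01 ± 0.04, 0.01 ± 0.07 and 0.11 ± 0.10 (adjusted p = 0.812, 0.976, 0.975 and 0.839). Limma called no gene, with or without a variance trend (0 of 4039, 286 at an unadjusted p under 0.05 where chance would give 202). Without the mutated library at 3600 s, 61 genes passed, among them *tnaA* (-0.55, adjusted p = 0.00468), *ynfF*, *ftnB* and *tnaB*. The terms shrank to -0.30 (*ynfF*), -0.15 (*ftnB*) and -0.24 (*tnaA*) without the 600 s period, and to -0.27 (*tnaB*) and -0.26 (*tnaA*) without the wild-type library at 3600 s. At the other end of the settings those of *ynfF* and *ftnB* reached -1.33 and -0.36.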

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

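The tests of the flagellar slopes over 4 libraries and all tests of the nitrate genes were chosen after the results were seen, and bounds of the NarL test were reworded after its value was seen, whereas the test of shrinking construct differences was set before.

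Of 196 groups of 6 libraries (98 named genes in each construct), 21 had 1 library whose gap to its nearest neighbour exceeded the 95% limit for its share of the group's range (10.7%), where chance alone would pick out about 1 in 20 groups. In 15 of them the library was the wild-type one at 3600 s. There *entC* stood at 5.99 against 3.71 to 4.0 in the other wild-type libraries (gap over range 0.87), *exbD* at 6.95 against 5.83 to 6.13 (0.73), *iscX* at 9.59 (0.728) and *ytfL* at 8.80 (0.65), all highest. It was the lowest library for *acrD* (0.839), *sucC* (0.777), *gadC* (0.725), *sdhB* (0.718), *lsrG* (0.696), *hdeA* (0.695), *proW* (0.668), *tnaB* (0.667), *tnaA* (0.653), *malE* (0.642) and *acnB* (0.639). Outside that library, *ompF* was highest at 900 s among the wild-type libraries (0.78), as was *flgD* (0.641), and *metN* was highest at 1200 s (0.651). Among the mutated libraries *cysU* was lowest at 1200 s (0.717). The 196 groups were not independent, because all genes of a construct share the same 6 libraries and many were named for their test results. A single library that stood apart is thus counted many times, so the share of 10.7% is no test against 1 in 20.

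The slope over period differed between constructs for *fliA* (-1.01), *flgI* (-0.95), *flgE* (-1.19), *flgD* (-1.14) and *flgG* (-1.15), and the median slope of the 53 flagellar genes was -0.473 in the mutated and -0.00555 in the wild-type libraries. The flagellar construct difference changed by -55.7% of its size per doubling. Draws of equally many other called genes of similar difference gave -13.5% to -0.121% (middle 95%), and the median of all other called genes was -3.07%. Differences of other genes thus shrank too, but by less. The flagellar genes were flagged for their slopes, and the draws took genes singly although genes of a list move together. This comparison therefore does not decide on a cause. A candidate explanation that stays open is a contrast of the mutated libraries at 600 s and 900 s with the others rather than a graded response. The list's medians there were 7.252 and 7.164, against 6.249 and 6.402 at 1200 and 1800 s and 5.689 and 5.647 at 2400 and 3600 s. Such a contrast alone leaves the further fall at 2400 and 3600 s undescribed. Whether these steps follow the period or cultures handled together was not tested. Over the 4 libraries from 1200 to 3600 s the median slope was -0.251, which keeps 53.1% of the slope over 6. Over the same 4 libraries *fliA* kept its slope (-0.91 in both), *flgD* (-1.10 against -1.16) and *flgE* (-1.10 against -1.21) nearly so, and *flgI* (-0.66 against -0.88) and *flgG* (-0.81 against -1.12) less, but these 5 were picked for their slopes and lost their calls there (*fliA* adjusted p = 0.451), and for the list the alternatives cannot be told apart with 1 library per period. A response of the mutated construct to the period itself remains open, untested. In the wild-type libraries the list's median was low (5.07 to 5.20), so their flat slope may also reflect low expression.

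In the mutated library at 600 s, *narK* stood at 13.02 against 7.71 to 8.56 in the other mutated libraries (gap over range 0.839) and *ynfF* at 8.68 against 10.18 to 11.06 (0.629). A wild-type library under a wrong label is argued against, since the smallest root mean square difference of this library to a wild-type library was 0.566 and the largest to another mutated library 0.429. Less oxygen in this culture as the only cause is argued against only for the 12 listed genes that Fnr activates and NarL represses. These lay at a median of -0.637 from the other 5 mutated libraries, where low oxygen alone would raise them. Less oxygen together with nitrate stays open. Also open, as a hypothesis found and tested on the same genes, is that nitrate-dependent regulation by NarL may have differed in this culture: the 10 NarL-activated genes tested had a median difference of 3.55, all above each of the other 5 mutated libraries, and the 12 NarL-repressed genes all lay below them. Outside both lists, *napA* stood at 11.91 against 8.98 to 9.54 in the other mutated libraries, and *nrfA* at 9.11 against 6.391 to 7.061. The uniform fall of the NarL-repressed list therefore depends on which genes were listed. No nitrate was named in the labels, and with 1 library a period of 600 s and a feature of this single culture are confounded.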

How the results depend on the processing

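The removal of the 3 libraries that stood apart was chosen after seeing the data, and all other settings were planned. Over the genes named, leaving out a library or period left direction and side of the threshold as they were in 2677 comparisons, weakened 62, strengthened 30 and reversed 39, and the other settings gave 1863, 57, 4 and 25. These comparisons are not independent, because for the construct effect leaving out a period or either of its libraries gives the same estimate. Construct counts were within 1.5 times of 830 and 769 in every setting but the requirement of a log2 change of at least 1 (89 and 39), with left-out libraries and periods giving 661 to 769 and 583 to 705. That requirement left 5 higher and 62 lower mutated slopes. The cause was not tested for the following changes unless stated.

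Quantile normalization gave 70 higher mutated slopes. The period in seconds gave 1 gene for the common trend, 1 higher and 29 lower mutated slopes and 0 differences of slope, and the frequency in Hz gave 2 higher differences of slope. Without the 3 libraries, 1 gene passed for the common trend, and 0 mutated slopes and 0 differences of slope did, although the differences of *fliA* (-1.06), *flgE* (-1.10) and *flgD* (-1.05) were about as large as with all libraries (-1.01, -1.19 and -1.14). Left-out libraries and periods gave 0 to 45 genes for any difference among periods (45 without the wild-type library at 600 s), 0 to 155 for the common trend (155 without the same library), 0 to 92 higher and 16 to 201 lower mutated slopes (0 and 16 without the mutated library at 600 s), 0 to 4 higher and 0 to 34 lower differences of slope (4 and 34 without the mutated library at 1200 s, 0 lower without the wild-type library at 600 s), and 0 to 61 for the intermediate-period response (61 without the mutated library at 3600 s). The higher differences were 3 without the wild-type library at 2400 s or the 1200 s period. With an estimated correlation 0 lists were called in the construct effect, 0 in the common trend and 0 in the difference of slopes. Fry called 9 lists for the common trend and 1 for the difference.

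Every reversal was in a value that the test had not called. Quantile normalization turned the *ompR* common slope to 0.0361 and its mutated slope to 0.0337. The period in seconds turned the wild-type slopes of *ompC* to 0.0182 and *hemA* to -0.000603. The frequency turned the wild-type slopes of *lacY* to -0.00941 and *flgE* to 0.0108 and the *csgD* difference to 0.0136. Without the 3 libraries, the *lacY* construct difference was 0.114, from only the periods that kept a library of both constructs. The common slopes became -0.0371 (*lacY*), 0.0163 (*hemA*), -0.00424 (*rpoS*), -0.0327 (*csgD*) and -0.0137 (*mqsR*). The wild-type slopes became 0.0541 (*envZ*), -0.0256 (*ompR*), -0.128 (*lacY*), -0.0259 (*csgD*), 0.00328 (*flgE*) and -0.0592 (*flgG*), and the mutated slopes 0.0269 (*hemA*) and -0.0455 (*csgD*). The differences became 0.0163 (*hemA*), -0.31 (*tnaA*), -0.0857 (*sucC*) and -0.0926 (*sdhB*).

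With libraries or periods left out, the common slope ranged from -0.0299 to 0.00976 for *ompR* and from -0.0427 to 0.0733 for *rpoS*. Wild-type slopes ranged from -0.224 to 0.0541 (*envZ*), -0.0256 to 0.0684 (*ompR*), -0.131 to 0.059 (*ompC*), -0.128 to 0.158 (*lacY*), -0.0209 to 0.0191 (*hemA*), -0.0259 to 0.116 (*csgD*), -0.143 to 0.0451 (*flgE*), -0.083 to 0.0423 (*flgD*) and -0.0592 to 0.0696 (*flgG*). Differences of slope ranged from -0.0257 to 0.321 (*lacY*), -0.113 to 0.0605 (*csgD*) and -0.168 to 0.567 (*tnaA*).

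Of the called values, *csgD* dropped to -0.12 with a pseudocount of 10, and without the 3 libraries *flgG* and *flgI* differed in slope by -0.75 and -0.73 and *fliC* had a mutated slope of -0.23, none of these 3 called. The 5 flagellar differences of slope kept their sign in every setting, and all 5 lost their call without the wild-type library at 600 s, without the 600 s period (*fliA* adjusted p = 0.132), without the 3600 s period (*fliA* adjusted p = 0.0725, *flgI* 0.0631), with the period in seconds and without the 3 libraries. Without the mutated library at 600 s *fliA* kept its call and the other 4 lost theirs at values no smaller than before (*flgI* -0.95 and *flgE* -1.28, adjusted p = 0.0567 each, *flgD* -1.22, adjusted p = 0.0729, and *flgG* -1.16, adjusted p = 0.0775). Depth limits nothing that can be stated, because the deposited values hold no counts.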

Other observations

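The tests of a shift between constructs and of the regulators Cra and cAMP-CRP were chosen after the results were seen, the bounds and gene matching of the regulator tests were revised after a first run had shown their values, which moved Cra from undecided to fitting and cAMP-CRP from excluded to undecided, and the lists and genes described for single libraries were picked after their values were seen, whereas the counts over other splits were set before.

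The wild-type library at 3600 s differed from the other 5 wild-type libraries in several gene groups at once. Of 33 iron acquisition genes, 25 lay above all 5 others (median difference 0.532), as did 47 of 54 ribosomal protein genes (0.538) and 8 of 9 fatty acid degradation genes (0.524). Of 22 genes for aerobic cytochrome oxidases and NADH dehydrogenase, 17 lay below all 5 others (-0.526), as did 13 of 21 heat shock genes (-0.435) and 22 of 40 genes for anaerobic respiration and fermentation (-0.351). The manganese superoxide dismutase gene *sodA* stood at 10.12 against 7.66 to 8.43, *iscS* at 13.27 against 10.71 to 12.50, and *grcA*, a glycyl radical protein gene, at 9.43 against 11.13 to 12.07. These are values of 1 library, without a test.

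The mutated library at 900 s also stood apart. Of 21 acid resistance genes, 15 lay above the other 5 mutated libraries (median difference 0.757), and 22 of 39 RpoS-dependent genes did (0.205), while 45 of 54 ribosomal protein genes lay below them (-0.325). In the mutated library at 600 s the nitrate reductase gene *narG* stood at 14.65 against 9.55 to 10.49 and the nitrite reductase gene *nirB* at 11.01 against 7.78 to 8.29, whereas the outer membrane protein gene *ompW* stood at 10.33 against 12.63 to 13.12.

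The joint rise of the fructose operon and glycolysis genes and fall of gluconeogenic genes in the mutated libraries raised the hypothesis of lower activity of Cra, a regulator that represses the former and activates the latter. The median difference over all genes was -0.00572, which the centring of the deposited values would give in any case, but one shift of all genes alike is argued against because both groups of Cra targets moved in opposite directions. Of 19 Cra-repressed genes 16 were higher and 1 lower, with a median of 0.663 against -0.163 to 0.182 for the middle 95% of 10000 matched random lists, and of 8 Cra-activated genes 6 were lower, with a median of -0.361 against -0.316 to 0.325. The difference of both medians, 1.02, has the direction that lower Cra activity would give. However, the second median lies close to its bound, and most repressed genes were among those that raised the idea. The 8 repressed genes outside the fructose operon and the glycolysis list had a median of 0.464 (random lists -0.245 to 0.252). Their values were split, with *epd*, *adhE*, *glk* and *ptsH* at 0.66 to 0.826 and *eda*, *ptsI*, *mtlA* and *edd* at -0.288 to 0.268. The median of so small and split a set does not decide on Cra. A change in cAMP-CRP activity cannot be told apart from none, because 14 of 21 called CRP-activated genes were higher and 7 lower, a share of 66.7% with an exact binomial 95% interval of 43% to 85.4%. The random lists and this interval treat genes as independent, which genes of the same operon are not, so both ranges may be too narrow.

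Other splits of the libraries gave the following counts. Exchanging the constructs within periods gave as many called genes in 1 of 32 splits, the real one (1599, highest other 3). No other split came near, and 1 of 32 is the smallest share this test can give. It cannot tell the plasmid from anything else that the cultures of a construct shared. For the slopes of the mutated libraries, 1 of 100 orders of the periods, the real one, gave as many (173, highest other 152). For the difference of slopes 3 of 100 did (17, highest other 22), so another order gave more. The same holds for the common trend at an unadjusted p under 0.05, where 2 of 100 did (869, highest other 891). The real order was thus among the highest, but these shares were not adjusted over the tests of this kind. With single libraries they cannot tell a response to the period from unusual cultures at the shortest periods, so chance is not excluded. At an unadjusted p under 0.05, 24 of 100 orders gave as many genes for the wild-type slopes (377, highest other 788). For the intermediate-period response 27 did (286, highest other 916). For any difference among periods, 22 of 100 pairings of mutated with wild-type libraries did (212, highest other 334). Chance cannot be excluded for any of these. The highest other counts of 788 and 916 are over 2 times the real ones, as a structure among the libraries not ordered by period could give, but no test here addressed such a structure. On component 1 the wild-type libraries at 600, 2400 and 3600 s lay at -14.6, -14.7 and -20.8. Those at 900, 1200 and 1800 s lay at -9.52, -7.93 and -9.14.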
